A study of Allium mongolicum with 12 samples.

How the data were processed

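RNA was measured by sequencing in roots of Allium mongolicum seedlings at 0, 24, 48 and 72 h of a saline-alkali treatment, with 3 libraries per time. Per the labels' protocols, seeds were germinated for 7 days, seedlings were grown for 45 days at 25 °C and moved to diluted Hoagland nutrient solution for 7 days before the treatment. Total RNA was extracted with TRIzol, libraries were made with a VAHTS Universal V6 kit, and paired reads of 150 bp were produced on an Illumina NovaSeq instrument, also per the labels. Whether the kit kept strand is not given in the sources used here. Reads were trimmed with Trimmomatic, per the submitters' processing notes, which give no version. The assembler, its settings, the aligner and the counting tool are not given in the sources used here.

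The deposited table holds estimated counts per feature, as its column headers name samples and its values show: 1 of 990048 values above 0 is exactly whole (tolerance 0), and library totals differ, from 23099287 to 26388120. Feature IDs have the form that the Trinity assembler gives to transcripts assembled without a genome, followed by a suffix from 1 to 4 whose meaning the file does not state. In 3686 faint features the values lay near whole multiples of a step that belonged to the feature, with a median of 2.66. Of the values above the first step, 79% lay within 0.2 of a multiple, where evenly spread values would give 40%. The features were chosen to have a gap above their lowest values, which raises the chance share above 40% by an amount not measured. Values near multiples are what a read count multiplied by a length ratio would give, a step that no header or label records. In these features a deposited count is larger than the number of steps behind it, and the spread expected from counting alone is larger by about the same step. Steps were not measured in abundant features. Intervals and floors stated in counts cover counting error only.

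All 12 columns were assigned to samples by their titles, and 0 were left unassigned. Estimated counts were rounded to whole numbers. Features with low counts were removed with edgeR's filterByExpr, which kept 76273 of 98328, and libraries were scaled with TMM factors. One quasi-likelihood model (edgeR 4.0.16 in R 4.3.3, glmQLFit and glmQLFTest) was fitted to all 12 libraries with a mean per group and 8 residual degrees of freedom. Pairs of groups were compared by two-sided contrasts, and all 4 groups by an F test, with Benjamini-Hochberg adjustment over the features tested in each comparison. A feature was called at an adjusted p below 0.05. These tests, the comparisons of each time with CK and with the time before it, the alternatives below and the rule for named features were fixed before the data were examined, and the comparison of 72 h with 24 h was added afterwards. The plan assumed raw counts, and rounding was added because the values were not whole. For a normalised unit the plan named limma on log2 values in place of edgeR. The values were taken as estimated counts, so edgeR was kept. CPM values are normalised by TMM. Where all libraries of a group were at 0, a fold was computed as a bound against 3 counts per library.

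The rule for named features was, for features with an ID only, to take the 2 with the largest mean rise and the 2 with the largest mean fall over the 3 comparisons with CK. They had to be called in all 3, have a mean CPM of at least 5 and have every treated library on the same side of every CK library. The file does not pair IDs with gene names, and no sequence or reference was used here. Lists of genes fixed in advance, among them phenylpropanoid, lignin, ion transport, osmolyte and hormone genes, were therefore not tested.

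The fit was tested on simulated counts with 200 changed features. For 24 h against CK (71362 features tested), 2% of 2-fold, 24% of 4-fold, 56% of 8-fold and 62% of 16-fold changes were recovered, with 2 false calls among 74. For 48 h (71346 features) the shares were 6%, 32%, 56% and 74%, with 2 false calls among 86, and for 72 h (71442 features) 4%, 22%, 60% and 72%, with 1 false call among 80. Most 2-fold changes were thus missed in simulations that changed 200 features and gave every group the same spread per feature. These shares need not hold for the data. There, 2675 of the 3618 features called at 72 h against CK changed at least 2-fold, and the rest changed less. Overlaps between comparisons that share the CK libraries were set against 20 simulations in which all 12 libraries were drawn around the CK means. These gave every group the same spread per feature.

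Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, and a stricter filter of at least 1 CPM in 3 libraries with a mean count of at least 10. Further ones were a replicate block, a fit on only the 2 groups compared, a minimum log2 change of 1 and leaving out each library in turn. Added after seeing the data were limma 3.58.1 with a variance per group, only features at a mean CPM of at least 5, library totals as the only scaling, the 24 h libraries averaged to 1 (with the features its own filter keeps, and with those kept by both filters), the F test without the 24 h libraries, and leaving out T48 replicate 2 where it is in neither group compared. Figures were drawn with matplotlib 3.10.9.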

Results

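Roots of Allium mongolicum, a perennial wild onion of dry steppe, were sampled before and during exposure to a mixed saline-alkali solution, and their RNA was sequenced. The solution combined 1 part sodium chloride, 9 parts sodium sulfate, 9 parts sodium bicarbonate and 1 part sodium carbonate at a total salinity of 150 mmol/L, so that high salt came together with high pH. The groups are unstressed control roots (CK, 0 h) and roots after 24 h (T24), 48 h (T48) and 72 h (T72), with 3 libraries each and 12 in all. No library of unstressed roots at 24, 48 or 72 h is among them. A difference from CK therefore cannot be told apart from a change with elapsed time, plant age or harvest. Each group drew on 20 seedlings, and the labels do not say how these were divided among the 3 libraries, so p-values measure only the spread between these libraries, which may be technical. The table holds estimated counts for 98328 assembled transcript features, identified by assembly IDs without gene names, and library totals ran from 23099287 to 26388120. A count of 3 corresponded to 0.114 to 0.13 CPM, where CPM is a count scaled to a common library total. No single feature took more than 1.09% of a library, and the 100 most abundant took 11.7% to 14.4%. The series names phenylpropanoid metabolism, the route to lignin and flavonoids, as its subject, but the features could not be assigned to that or any other pathway here.

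On the first principal component of log2 CPM over 20621 features (31.1% of the variance), control roots lay at one side and 24 h and 72 h roots at the other. The CK libraries lay between -87.4 and -51.9, the T24 libraries between 33.4 and 34.2, and the T72 libraries between 28.9 and 60.4. T48 replicates 1 and 3 lay at 4.9 and 17.4, while T48 replicate 2 lay at -58.9, among the controls. On the second component T48 replicate 2 lay at -14.8, between the CK libraries (4.3 to 37.1) and T48 replicates 1 and 3 (-79.7 and -49.2). Across features, T48 replicate 2 had a mean correlation of 0.892 with the CK libraries and 0.85 with the other 48 h libraries. The 24 h libraries were far closer to each other than those of any other group, with a mean correlation of 0.988 to 0.989. The biological coefficient of variation (common dispersion) was 8.3% at 24 h, 36.6% in CK, 38.3% at 48 h and 27.6% at 72 h. The main fit takes a single spread per feature from all 12 libraries, so its assumption of equal spread does not hold. Its p-values for comparisons between CK, 48 h and 72 h rest partly on the narrow 24 h spread and may be too small. The 24 h libraries still differed by more than counting noise, with a chi-square of 5106 on 3848 degrees of freedom over 1924 faint features (ratio 1.33, against 2.24 to 2.88 in the other groups). Libraries made from a single RNA pool would also exceed counting noise, so this does not show 3 separate samples. They were kept as 3, as the labels give them, and each count is also given with their average entered as 1 library.

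**Figure D1:**
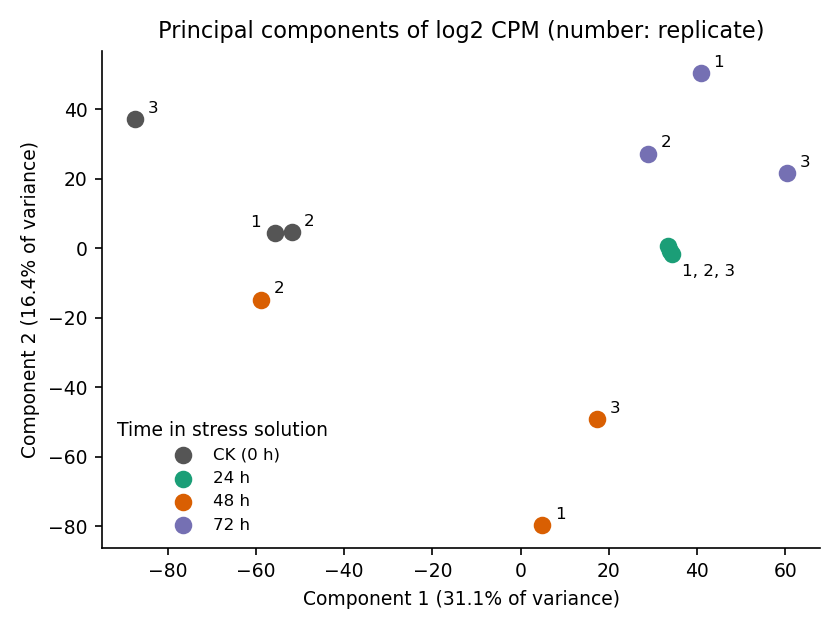
The 12 root libraries on the first (horizontal, 31.1% of variance) and second (vertical, 16.4%) principal component of log2 CPM over 20621 features, in arbitrary units, with replicate numbers beside the points. The 3 libraries at 24 h fall almost on one point, and T48 replicate 2 (-58.9) lies within the horizontal range of the CK libraries (-87.4 to -51.9).

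**Figure D2:**
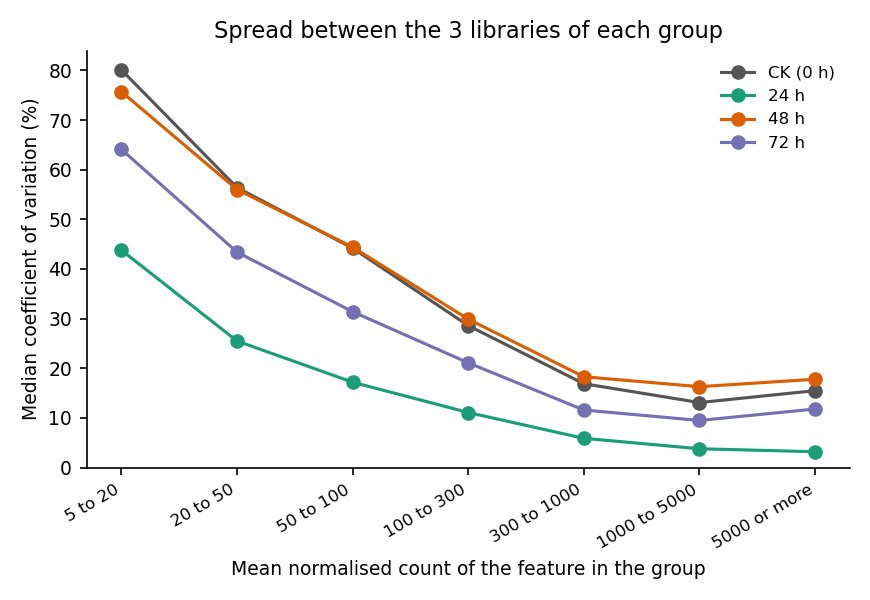
Median coefficient of variation (vertical, percent) between the 3 libraries of each group for features binned by their mean normalised count in that group (horizontal). At 300 to 1000 counts the 24 h libraries varied by 5.9%, against 16.9% in CK, 18.3% at 48 h and 11.6% at 72 h.

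After 24 h in the saline-alkali solution, 1999 features were higher and 1146 lower than in control roots, of 76273 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of the 1999 rises, 1402 (70.1%) had a mean CPM below 5, close to the 73% of tested features at that level, against 13.6% of the falls. No count was seen in any CK library for 687 of them (1852 of all tested features), and 881 had at most 3 counts in each of the 9 libraries of the other times (1372 of all tested). With the features at 0 in CK set to their bound against 3 counts per library, the median rise was 3.09 on the log2 scale. The fitted median was 6.29, which depends on the prior count. Suffix 1 of the feature IDs, carried by 30.4% of tested features, was carried by 68.1% of the higher ones. Among abundant features the balance was the opposite: at a mean CPM of 100 or more, 174 fell and 63 rose of 1911, with median log2 changes of -1.05 and 0.97. This excess of falls also held with median-of-ratios (RLE) size factors (179 and 59) and with library totals as the only scaling (131 and 97). At 20 to 100 CPM, 520 fell and 225 rose, but with library totals alone 350 fell and 358 rose. Library totals alone placed the median of all features at 0.215 on the log2 scale, in place of 0.078, and called 2528 features higher and 801 lower. All 3145 called features had their 3 treated libraries on one side of the 3 CK libraries, as did 33.7% of all tested features. Chance gives 10% where all libraries are independent. It gives more where the near-identical 24 h libraries are not, so no excess is read from this share. With the 24 h libraries averaged to 1, edgeR called 0 features, and 4670 of 93129 tested had an unadjusted p below 0.05, about the 5% that chance gives (15238 of 76273 with all 12 libraries). On the 76208 features kept by both filters it also called 0, with 6.4% at an unadjusted p below 0.05. Both averaged fits take the spread of the lone 24 h sample from the other groups, which makes calls unlikely by design. DESeq2 and limma on all 12 libraries called 8235 and 6287, and edgeR on the CK and 24 h libraries alone 6789. The count was 302, 309 or 357 without T24 replicate 1, 2 or 3, 2029 without CK replicate 1, 1346 without CK replicate 3 and 5233 without T48 replicate 2.

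After 48 h, 288 features were higher and 239 lower than in control roots (edgeR, adjusted p below 0.05). The rises had a median of 2.04 on the log2 scale with the 36 features at 0 in CK set to their bound, and the falls a median of -1.15. Of the rises, 130 (45.1%) were of features below a mean CPM of 5, against 73% of tested features, and 36.8% carried suffix 4, against 24.9% of tested features. There were 51 features with at least 50 counts in every 48 h library and at most 3 in every CK library, and 0 of the converse kind. At a mean CPM of 100 or more, 32 features fell and 18 rose, and 39 fell and 16 rose with RLE factors, but the balance turned to 21 falls and 27 rises with library totals alone. Over all features library totals called 378 higher and 163 lower, with the median of all features at 0.146 in place of 0.05. The 527 called features all had their groups apart, as did 14.8% of all tested features. The comparison rested heavily on T48 replicate 2: without it 1179 features were higher and 1806 lower. Without T48 replicate 1 or 3 it gave 79 or 65, without CK replicate 1 or 3 it gave 294 or 213, and with the 24 h libraries averaged it gave 1. Fitted on the CK and 48 h libraries alone, which takes away the narrow 24 h spread and also degrees of freedom, edgeR called 4 features. In that fit 5356 of 57993 features had an unadjusted p below 0.05. On all 12 libraries DESeq2 called 4925 and limma 102. The balance of rises and falls was not stable: falls led with DESeq2 (2537 and 2388), limma (58 and 44) and features at 5 CPM or more (892 and 550), and without CK replicate 1 (179 and 115) or CK replicate 3 (138 and 75).

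After 72 h, 1568 features were higher and 2050 lower than in control roots (edgeR, adjusted p below 0.05), with median log2 changes of 1.49 and -1.49 once features at 0 in a group were set to their bound. Falls outnumbered rises among abundant transcripts. At a mean CPM of 100 or more, 305 of 1911 features fell and 91 rose, with medians of -1.37 and 1.1, and 20.72% of these features were called. At 20 to 100 CPM 893 fell and 410 rose, at 5 to 20 CPM 449 fell and 505 rose, and below 5 CPM 403 fell and 562 rose. Only 1.73% of features below 5 CPM were called. Higher counts make a call easier, and a fall is hard to detect near the floor. The change of balance with level may thus partly reflect detection. The excess of falls at 100 CPM or more held with RLE factors (321 and 81) and with library totals alone (270 and 135), and at 20 to 100 CPM as well (1012 and 369, and 702 and 607). Over all features the balance turned with library totals alone, to 2205 higher and 1662 lower, with the median of all features at 0.189 in place of 0.056. The groups were apart for 3610 of the 3618 called features and for 24.8% of all tested features. Entering the 24 h libraries as 1 lowered the count to 665, leaving out T48 replicate 2 raised it to 5509, DESeq2 gave 9245 and edgeR on the CK and 72 h libraries alone 2205. Without CK replicate 3 it was 2174, and without T72 replicate 1, 2 or 3 it was 1110, 2056 or 1147.

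**Figure D3:**
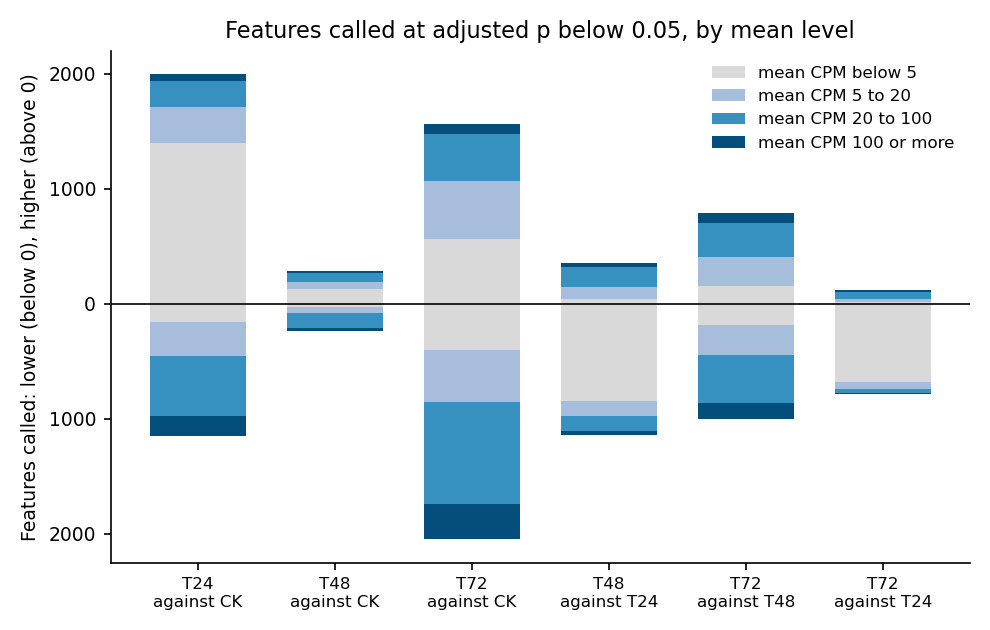
Features called at an edgeR adjusted p below 0.05 in each comparison (horizontal), counted upward where higher and downward where lower in the first-named group, with bars shaded by the feature's mean CPM over 12 libraries. At 24 h against CK 1402 of the 1999 rises lie below 5 CPM, while at 100 CPM or more 174 features fell and 63 rose (131 and 97 when libraries are scaled by their totals alone).

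Between 24 h and 48 h, 1144 features fell and 356 rose (edgeR, adjusted p below 0.05). Of the falls, 842 (73.6%) were below a mean CPM of 5, as were 73% of tested features. Suffix 1 was carried by 838, 533 had no count in any 48 h library (2046 of all tested), and the median fall was -4.22 on the log2 scale with those at their bound. Among features at 100 CPM or more the counts were near even, with 34 falls and 38 rises (35 and 35 with RLE factors, 49 and 44 with library totals alone). Of the 1999 features higher at 24 h, 871 were lower at 48 h than at 24 h, and of the 1146 lower at 24 h, 164 were higher at 48 h than at 24 h. However, 881 of the 1999 had at most 3 counts in each of the 9 libraries of the other times. These passed the filter through the 24 h libraries alone, so their lower level at 48 h was fixed in advance. The count of 1500 became 0 with the 24 h libraries averaged, where 3.6% of features had an unadjusted p below 0.05 and chance gives 5%. DESeq2 and limma on all 12 libraries called 4998 and 4186, and edgeR on the 24 h and 48 h libraries alone 4050. It was 209, 208 or 262 without T24 replicate 1, 2 or 3 and 792 without T48 replicate 1, and with only features at 5 CPM or more 490 fell and 499 rose.

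Between 48 h and 72 h, 1002 features fell and 792 rose (edgeR, adjusted p below 0.05), with medians of -1.51 and 1.31 on the log2 scale. These changes reached abundant transcripts: at 100 CPM or more 141 fell and 91 rose, and at 20 to 100 CPM 412 fell and 294 rose, with falls in excess at both levels under RLE factors and library totals alone as well. Fitted on the 48 h and 72 h libraries alone, edgeR called 0 features, with 8385 of 61924 at an unadjusted p below 0.05, while DESeq2 called 5598 and limma 1803 on all 12. The count of 1794 was 1039 without T48 replicate 1, 343 without T72 replicate 1, 598 without T72 replicate 3 and 172 with the 24 h libraries averaged. Rises led in 2 alternatives, with 190 rises and 153 falls without T72 replicate 1 and 718 rises and 705 falls without T48 replicate 2.

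The comparison of 72 h with 24 h was added after the data were seen, because T48 replicate 2 stood apart. At 72 h, 783 features were lower than at 24 h and 116 higher (edgeR, adjusted p below 0.05). Of the lower ones, 679 (86.7%) were below a mean CPM of 5, against 73% of tested features, 621 carried suffix 1 and 446 had no count in any 72 h library (1837 of all tested), and the median fall was -4.95 with those at their bound. At 100 CPM or more 10 features were higher and 10 lower. Of the features higher at 24 h, 682 were lower at 72 h than at 24 h and 593 were also called higher at 72 h than in CK. Only 116 of the 682 exceeded 3 counts in any of the 9 libraries of the other times. Of the 1118 features higher at 24 h that did so, 91.2% had a fitted change above 0 at 72 h against CK. Of the features lower at 24 h, 14 were higher at 72 h than at 24 h and 762 were also called lower at 72 h than in CK. The changes at 24 h and 72 h are measured against the same CK libraries, which alone favours a shared sign. No persistence is therefore read from the 91.2% or from the shared calls. With the 24 h libraries averaged the count fell from 899 to 0, where 2.8% of features had an unadjusted p below 0.05 and chance gives 5%. DESeq2 and limma on all 12 libraries called 3230 and 5767, and edgeR on the 24 h and 72 h libraries alone 5496. Leaving out T24 replicate 1, 2 or 3 gave 136 to 182, T72 replicate 1, 2 or 3 gave 341, 494 or 463, and T48 replicate 2 gave 1372.

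Over the 4 times together, 6209 of the 76273 features (8.1%) differed in edgeR's F test at an adjusted p below 0.05. Classed by the tests of successive steps, 1025 rose in the first step with neither later step called, 775 rose and then fell by 48 h, and 766 fell in the first step with no later call. Another 548 fell and 477 rose only in the step from 48 h to 72 h, and 202 fell in both the first and the last step. Among the 1999 features higher at 24 h, 881 had at most 3 counts in each of the 9 libraries of the other times. Their fall after 24 h was fixed in advance, and how many of the 775 are among them was not counted. The 775 are therefore not read as a time course. A step with no call is not shown to be unchanged. The count of 6209 was 2090, 1998 or 2040 without T24 replicate 1, 2 or 3, 3361 without T72 replicate 1, 4014 without T72 replicate 3, 286 with the 24 h libraries averaged and 14992 with DESeq2.

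At both 24 h and 72 h, 593 features were higher and 762 lower than CK (879 and 544 with library totals as the only scaling), against 41.1 and 30.8 for independent lists of these lengths. In 20 simulations of unchanged groups against shared controls, 0 features were called at both times. The simulations gave every group the same spread, as the test assumes, so a value near 0 was largely fixed in advance. Across 20621 features, which are not independent replicates, log2 changes at 24 h and 72 h had a Pearson correlation of 0.696 (Spearman 0.769), and the simulations gave 0.498. Their covariance was 0.448, against 0.073 in the simulations. For 24 h and 48 h the correlation was 0.563 (simulated 0.501) and the covariance 0.292 (simulated 0.073), and for 48 h and 72 h these were 0.535 (0.499) and 0.294 (0.073). The biological coefficient of variation was 36.6% in CK, 8.3% at 24 h, 38.3% at 48 h and 27.6% at 72 h. Shared controls that vary more than a treated group raise the correlation with no change, so no excess is read from the correlations. The simulated covariance may be too low for the same reason. The 3 CK libraries do not give 2 parts of at least 2 libraries each, so the controls were not split. Part of the excess in shared calls and in covariance may come from them. The count of 1355 at both times was 594 without CK replicate 3, 120, 130 or 143 without T24 replicate 1, 2 or 3, 2713 without T48 replicate 2, and 618, 881 or 630 without T72 replicate 1, 2 or 3. It was 0 with the 24 h libraries averaged, where no feature passed at 24 h, 4132 with DESeq2 and 2044 with limma. Higher features outnumbered lower ones without CK replicate 1 (472 and 464), CK replicate 2 (579 and 415) or T24 replicate 1, 2 or 3 (72 and 48, 78 and 52, 86 and 57).

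At all of 24 h, 48 h and 72 h, 81 features were higher and 52 lower than CK, against 0 in the 20 simulations, which gave every group the same spread. With library totals as the only scaling these were 122 and 26. The count of 133 was 6 without T24 replicate 1, 2 or 3, 31 or 23 without T48 replicate 1 or 3, and 1128 without T48 replicate 2. It was 74 or 49 without CK replicate 1 or 3, 63 or 53 without T72 replicate 1 or 3, 1269 with DESeq2 and 0 with the 24 h libraries averaged. Lower features outnumbered higher ones without T48 replicate 2 (742 and 386) or T72 replicate 2 (51 and 43), with limma (34 and 12) and at 5 CPM or more (248 and 155). Of the 133 features, 44 that rose and 50 that fell had a mean CPM of at least 5 and every treated library on one side of every CK library, and the 2 largest mean rises and 2 largest mean falls among them are named here by their assembly IDs.

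TRINITY_DN33907_c0_g1_i11_1 rose from 1.07 ± 0.589 CPM in CK (SD, n = 3) to 17 ± 1.67 at 24 h, 27.1 ± 14.6 at 48 h and 16.4 ± 5.36 at 72 h. Its log2 changes against CK were 3.97 (SE 0.52), 4.64 (SE 0.54) and 3.92 (SE 0.52), with edgeR adjusted p of 0.0047, 0.0086 and 0.0034. In T48 replicate 2 it stood at 10.2 CPM, the lowest of the 48 h libraries and above the highest CK library (1.75). TRINITY_DN43899_c0_g1_i2_1 rose from 0.539 ± 0.263 CPM to 11 ± 0.509, 4.6 ± 2.94 and 4.71 ± 2.14 at the same times, with log2 changes of 4.33 (SE 0.62), 3.08 (SE 0.59) and 3.11 (SE 0.59). Its edgeR adjusted p were 0.0061, 0.046 and 0.016, and in T48 replicate 2 it stood at 1.39 CPM against at most 0.832 in CK. TRINITY_DN33883_c0_g2_i1_3 fell from 22.1 ± 7.7 CPM in CK to 2.89 ± 0.546 at 24 h, 2.81 ± 0.696 at 48 h and 4.41 ± 0.771 at 72 h. The log2 changes were -2.93 (SE 0.32), -2.97 (SE 0.32) and -2.32 (SE 0.31), with edgeR adjusted p of 0.0026, 0.0086 and 0.0035. TRINITY_DN29916_c1_g1_i1_3 fell from 25 ± 19 CPM to 3.45 ± 0.0545, 4.09 ± 0.516 and 4.81 ± 0.923, with log2 changes of -2.86 (SE 0.52), -2.61 (SE 0.51) and -2.38 (SE 0.51). Its edgeR adjusted p were 0.016, 0.049 and 0.025, and its CK libraries ranged from 6.46 to 44.5 CPM. None of the 4 passed the test between any 2 of the treated times, with adjusted p of 0.29 or more. With the 24 h libraries averaged, the log2 changes at 24 h were 3.99, 4.36, -2.9 and -2.84 in the order given, near those of the main fit. The calls were lost there, where the spread of a lone sample is taken from the other groups. Over 18 alternatives at 24 h the lowest adjusted p came from DESeq2, at 1.8e-12, 1.4e-10, 2.8e-15 and 2.8e-06. At 48 h TRINITY_DN43899_c0_g1_i2_1 and TRINITY_DN29916_c1_g1_i1_3 lost the call in 11 and 12 of 17 alternatives, and at 72 h in 5 and 9 of 18. None of the 4 changed direction, which the rule that chose them largely fixed in advance. TRINITY_DN33907_c0_g1_i11_1 lost the call at 48 h in 4 of 17, fitted on 2 groups (adjusted p 0.13), with limma (0.1) and with the 24 h libraries averaged under either filter (0.1 and 0.09). TRINITY_DN33883_c0_g2_i1_3 lost it there in 3 of 17, fitted on 2 groups (0.13) and with the 24 h libraries averaged (0.092 and 0.075). Among single libraries left out, TRINITY_DN43899_c0_g1_i2_1 lost the call at 48 h without CK replicate 1, 2 or 3 or T48 replicate 1 or 3 (adjusted p 0.062 to 0.12, against 5.4e-05 to 0.31 over all alternatives). At 72 h it lost the call without CK replicate 3 (0.056) or T72 replicate 3 (0.061), where all alternatives spanned adjusted p of 1.6e-05 to 0.098. TRINITY_DN29916_c1_g1_i1_3 lost the call at 24 h without T24 replicate 1, 2 or 3 (adjusted p 0.09 to 0.098) and at 48 h without CK replicate 2 or 3 or T48 replicate 1, 2 or 3 (0.052 to 0.15, against 5.8e-05 to 0.29 over all alternatives). At 72 h it lost the call without CK replicate 3 or T72 replicate 1, 2 or 3 (adjusted p 0.073 to 0.1, against 0.00011 to 0.1 over all alternatives), and without CK replicate 3 its changes shrank to -2.15 at 24 h, -1.91 at 48 h and -1.67 at 72 h. Each ID is an assembled transcript, so its count is uncertain where other assembled forms or close copies share its reads.

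**Figure D4:**
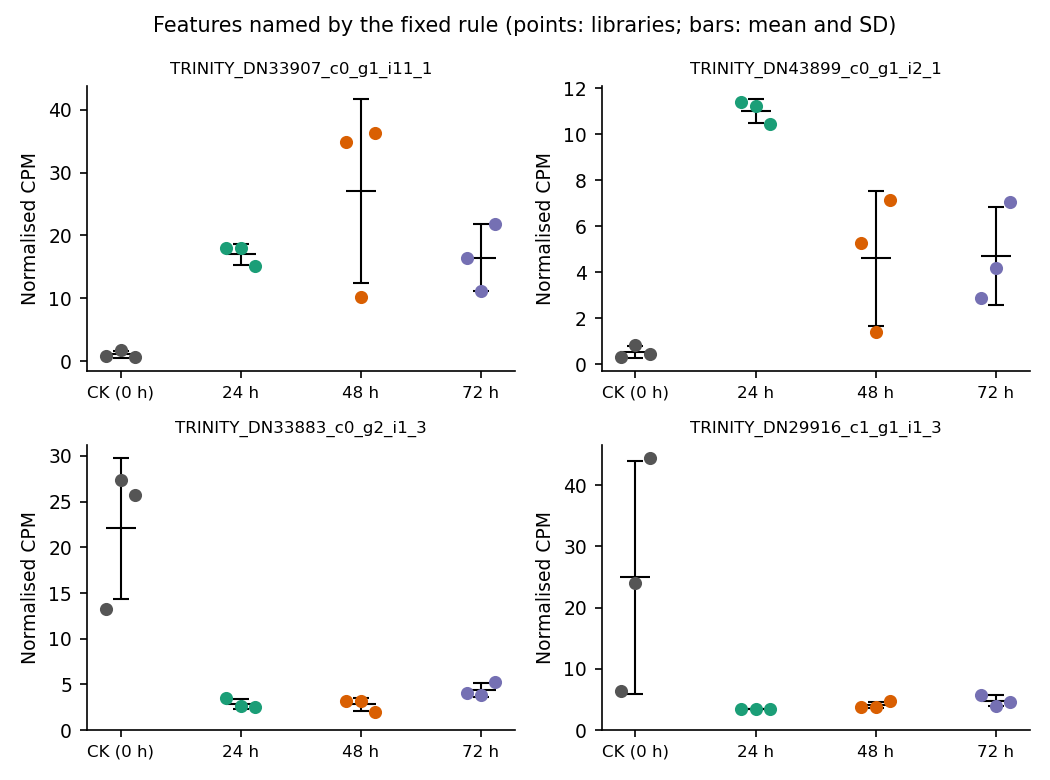
Normalised CPM (vertical) of the 4 features named by rule in each library (points) at 0, 24, 48 and 72 h (horizontal), with horizontal bars for group means and whiskers for the SD (n = 3). The upper 2 rose from 1.07 and 0.539 CPM in CK, and the lower 2 fell from 22.1 and 25 CPM to at most 4.81 CPM on average.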

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

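The comparison of 72 h with 24 h was chosen only after the result was seen, as were the tests of a shared assembly, of a CK library under a T48 label, of 1 RNA pool, of depth, of the ID suffix as an assembly, of suffix 1 by level and of splits without the 24 h libraries. The change against CK differed between times, by a test of the difference itself, for 1500 features between 48 h and 24 h, 1794 between 72 h and 48 h and 899 between 72 h and 24 h. The first and last counts were 0 with the 24 h libraries averaged to 1 library, which changes their number and their spread together. In that fit 3.6% and 2.8% of 93129 features had an unadjusted p below 0.05, where chance gives 5%. On all 12 libraries DESeq2 called 4998 and 3230 and limma 4186 and 5767. The second was 172 with that change and 343 without T72 replicate 1, 598 without T72 replicate 3 and 1039 without T48 replicate 1. Leaving out T24 replicate 1, 2 or 3 gave 209, 208 or 262 for the first and 136 to 182 for the last. The first was also 792 without T48 replicate 1, and the last 341, 494 or 463 without T72 replicate 1, 2 or 3 and 1372 without T48 replicate 2.

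Libraries at 3 against 3 make 10 splits, too few for a share below 0.05. Fitted on 2 groups alone, the labelled split was the only 1 of 10 to reach its own count in 5 comparisons. These counts were 6789 for 24 h against CK, 4 for 48 h against CK, 2205 for 72 h against CK, 4050 for 48 h against 24 h and 5496 for 72 h against 24 h, and the highest other split called 0 in each. For 72 h against 48 h the labelled split called 0, so all 10 reached it, and the highest other called 39. That split set T48 replicates 1 and 3 with T72 replicate 3 against the rest, which points to a structure within the groups. For the F test over 4 times, the labelled split called 6209 features and the highest other of 40 drawn splits 846, but splits that part the near-identical 24 h libraries raise the fitted spread, so this count does not bear on chance. Among the 9 libraries of CK, 48 h and 72 h alone, the labelled split was the only 1 of 100 drawn to reach its count of 574, and the highest other called 255. That other split again set T48 replicates 1 and 3 with T72 replicate 3. An arbitrary grouping of these libraries is thus unlikely. Since the libraries of a group may be technical, and parting alike libraries raises the fitted spread here too, this does not test the treatment.

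T48 replicate 2 lay with the CK libraries on the first principal component and by correlation, though not on the second component. In each set of features by ID suffix its lowest correlation with a CK library exceeded its highest with another 48 h library, by at least 0.009 in suffixes 1, 3 and 4, which argues against an assembly shared with CK replicate 2. No CK library was out of place in turn (highest difference -0.051), which argues against a swap with CK. Of 80, 103 and 73 features with at least 50 counts in T48 replicates 1 and 3 and at most 3 in all CK libraries but replicate 1, 2 or 3, T48 replicate 2 held 58, 61 and 54 at 50 counts or more and the CK library left out 1, 11 and 2, which argues against a CK library mislabelled after preparation. Whether its plants had responded little, or were exchanged before RNA extraction, stays open, since the values point both ways. Unstressed plants would lack these shared 48 h features if they are a response of the plant, which was not tested. On an axis from the mean of 2 CK libraries (0) to that of 24 h and 72 h (1), however, T48 replicate 2 stood at 0.3. This is within the range of 0.14 to 0.36 that each CK library took when placed against the 2 others, while T48 replicates 1 and 3 stood at 0.69 and 0.78.

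In faint features the 24 h libraries differed by little more than counting noise (chi-square ratio 1.33). Their variance over mean was 2.67 to 3.02 up to 1000 counts, 3.73 at 1000 to 5000 and 12.06 at 5000 counts or more. The median step of 2.66 was measured in faint features only, so the counting noise of more abundant features is not known. Depth does not account for the narrow spread at 24 h: mean totals were 1.009 times those at 72 h, while the variance over mean at 100 to 300 counts was 3.55 times as large at 72 h as at 24 h. A candidate explanation is a single RNA pool behind the 3 libraries, since 0 features were private to a single 24 h library (at least 50 counts there and at most 1 in the 11 others). Each of the other 9 libraries had between 7 and 290. Plants that responded uniformly after 24 h were not tested and stay open.

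Of the 1999 features higher at 24 h, 1361 carried suffix 1 (68.1%, against 30.4% of tested features), while their level was that of the catalogue (70.1% below 5 CPM, against 73%). The share with suffix 1 was 79.8% below 5 CPM, 45.3% at 5 to 20 CPM (exact Clopper-Pearson 95% interval 39.7 to 51), 36% at 20 to 100 CPM (29.7 to 42.6) and 33.3% at 100 CPM or more (22 to 46.3), against 31.6%, 27.4%, 27.1% and 26% of tested features. At 20 to 100 CPM the 27.1% of tested features lies below the interval, which argues against an effect of the catalogue on faint features only. The shares are what an effect that fades as the level rises would give. These intervals treat features as independent draws, which they are not, so the argument is weaker than they imply. Features private to 1 library carried a single suffix in 9 of 9 libraries (100% each, 645 features), as if each suffix marked a separate assembly of some libraries. A transient response of the plant was not tested, and sequences from another organism or genotype in the 24 h material cannot be told apart from transcripts of the plant that appear at 24 h without the sequences themselves: of 699 features with a rise of 16-fold or more, 75.5% were at or below 3 counts in the 9 other libraries.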

How the results depend on the processing

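The limma fit, the level, totals-only and averaging alternatives, the F test without 24 h, the omission of T48 replicate 2 from comparisons it is not in, and the 72 h against 24 h and 24 h with 72 h results were chosen only after the result was seen. RLE factors and library totals alone kept the total of each count within 1.5 times, though not its split by direction or level. For each change the cause was not tested unless stated. In the order 24, 48 and 72 h against CK, 48 h against 24 h, 72 h against 48 h and 72 h against 24 h, the counts were 3145, 527, 3618, 1500, 1794 and 899. DESeq2 raised all 6, to 8235, 4925, 9245, 4998, 5598 and 3230, the F test from 6209 to 14992, shared calls at 3 times from 133 to 1269 and at 24 and 72 h from 1355 to 4132. With the 24 h libraries averaged, where a lone sample is assumed to vary like the other groups, they were 0, 1, 665, 0, 172 and 0, 286 for the F test and 0 for both shared counts. That fit tested 93129 features, and behind the 0 values 5%, 3.6% and 2.8% had an unadjusted p below 0.05, where chance gives 5%. On the 76208 features kept by both filters the counts were 0, 1, 823, 0, 247 and 0, 343 for the F test and 0 for both shared. The F test over CK, 48 h and 72 h alone called 574, with fewer samples and times. Fits on the 2 groups gave 6789, 4, 2205, 4050, 0 and 5496. With limma the counts at 24 h and 48 h against CK, 48 h against 24 h and 72 h against 24 h were 6287, 102, 4186 and 5767, with 46 shared at 3 times and 2044 at 24 and 72 h. Features at 5 CPM or more gave 1442 at 48 h against CK, 989, 2910 and 154 for the 3 differences between times and 403 shared at 3 times. They also turned the split at 24 h to 975 higher and 1791 lower and that of 48 h against 24 h to 499 higher and 490 lower. No filter gave 288 at 48 h against CK, 62 shared at 3 times and 898 at 24 and 72 h, a stricter filter 968 and 244, and a 2-fold minimum 81 shared at 3 times.

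With a replicate block the counts were 1474 and 98 at 24 h and 48 h against CK, 686 for 48 h against 24 h, 267 for 72 h against 24 h, 3229 for the F test, 28 shared at 3 times and 787 at 24 and 72 h. Of 18 same-numbered pairs of libraries, 3 had deviations correlated above 0.1 (mean -0.005), and 3 of 12 libraries correlated best with their own number, so the numbers were not taken to pair the samples.

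Leaving out 1 library at a time gave 302 to 5233 at 24 h, 65 to 2985 at 48 h and 1110 to 5509 at 72 h against CK, 208 to 1375, 343 to 1759 and 136 to 1372 between times, 1998 to 8835 in the F test, 6 to 1128 shared at 3 times and 120 to 2713 at 24 and 72 h. The highest values at 24, 48 and 72 h against CK, in the F test and in both shared counts came without T48 replicate 2. For the 4 named features, 157 of 212 alternative values kept the call, 55 lost it and 0 changed direction. The rule that chose them set every treated library on one side of every CK library, so a change of direction was hardly possible. Gene lists fixed in advance, with their alternatives, were not run, since the features have no gene names here. A count of 3 per library is 0.114 to 0.13 CPM. In simulated data at most 6% of 2-fold changes were recovered, and depth was not varied there.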

Other observations

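The test of shared features was chosen only after the result was seen. Of 66 features at 50 counts or more in T48 replicates 1 and 3 and at most 3 in every CK library, 62 were above 3 counts and 51 at 50 or more in T48 replicate 2, at a median of 1.57 times the mean of the other 48 h libraries. Of the 51, 22 carried ID suffix 2 and 29 suffix 4. By the same limits, 496 features were on at 24 h and off in CK, 426 of them with suffix 1.

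Private features, at 50 counts or more in 1 library and at most 1 in the 11 others, were most numerous in T48 replicate 1 (290, all with suffix 4, 0.13% of its counts) and T48 replicate 2 (265, all with suffix 2, 0.145% of its counts). The other 7 libraries that had any held 7 to 32. As a group the 24 h libraries shared 428 features that were at 50 counts or more in all of them and at most 3 in the 9 others, 383 with suffix 1 and 45 with suffix 2, together 0.23% of their counts. The other 3 groups shared 0 such features. The 24 h libraries also had the most features above 0, with 88222 to 88822, against 75623 to 83036 in all others.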
